A study of Mus musculus with 36 samples.

How the data were processed

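Plasma miRNA was measured in 36 female mice on Agilent single-colour arrays of mouse miRNAs labelled with Cy3, 1 array per mouse. Per the labels, total RNA was extracted from plasma with the Qiagen miRNeasy column kit, and each sample carries a genotype, an age, a processing batch, the absorbance of the plasma at the haemoglobin band as a read-out of haemolysis, and a yes or no call of haemolysis. Per the file headers, images were quantified with Agilent Feature Extraction 10.7.3.1 on a design annotated to mm9, with background detrending within each array and no scaling between arrays. The deposited scanner intensity values are therefore background-subtracted spot brightness on a linear scale, and they can be negative. A deposited table of log2 values, 1 per miRNA and array, was also used. How it was made is not given in the sources used here. Its column medians ran from 2.98 to 4.78.

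Each mouse was assigned to 1 of 6 groups by the genotype and age in its label, and each array is a separate animal per the labels. Some labels leave room for doubt. The tumour grade of 2 NeuT- mice aged 6 weeks names dysplasia, that of 1 NeuT+ mouse of 6 weeks is a remark on a repeat beside a burden of 0, and the CI in the titles of 3 NeuT- mice of 6 weeks is not explained. All were kept in the group of their genotype label, which was not checked. Replicate numbers within a group follow no label and pair no samples. No 2 of the 630 pairs of arrays held identical values, and the highest correlation between arrays was 0.999.

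Control spots and spots flagged by the scanner software as non-uniform or population outliers were left out, and spots of 1 probe were averaged. The probe with the highest mean over the 36 arrays stood for each of the 1247 miRNAs. A miRNA counted as detected by the scanner software's own call. Only 1 miRNA was detected on all 36 arrays, so each array was divided by the 75th percentile over the 7 miRNAs detected on at least 33 arrays, the fallback fixed in advance. These 7 included miR-451a and miR-15a-5p. The largest array factor was 952 times the smallest. A floor was then set at 0.018 of the array's percentile and log2 taken. Of the values of tested miRNAs, 54.2% in batch 1 and 44.2% in batch 2 lay at the floor, while 88.2% and 16.7% were detected, so many batch 2 values above the floor were scaled background. Values at the floor carry no order. On every array 2 tested miRNAs, miR-17-5p and miR-140-3p, lay at it, and in all 12 mice aged 12 weeks 71 did, for which any fitted genotype difference at that age comes from the absorbance term alone.

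The 223 miRNAs detected in at least 75% of the arrays of at least 1 group were tested with limma 3.58.1 in R 4.3.3 (statmod 1.5.0). All 36 arrays entered 1 fit of the 6 group means, batch and log2 absorbance, with 28 residual degrees of freedom and trended, robust empirical Bayes. Benjamini-Hochberg adjusted p under 0.05 was the threshold. The genotype effect was the NeuT+ minus NeuT- difference at each age and its average over the 3 ages with equal weight. Of the 15 miRNA lists fixed in advance, 12 were tested with camera at a preset correlation of 0.01 and again with an estimated correlation. They were erythrocyte and haemolysis, platelet and endothelium, myeloid, lymphoid, liver, epithelium, breast tumour oncomiRs, breast tumour suppressor miRNAs, miR-17-92 and paralogues, let-7 family, miR-30 and miR-29 families, and the Dlk1-Dio3 cluster. The muscle list had 1 tested member, and the pancreas and brain and the viral lists had 0, so these were not tested. List medians and counts describe members that were tested.

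Named miRNAs followed a rule fixed in advance. Up to 10 calls per direction with the smallest p were named and, where fewer than 5 passed, those with the smallest unadjusted p up to 5, said not to have passed. MiR-451a, miR-16-5p, miR-144-3p, miR-486-5p, miR-21a-5p, miR-122-5p and miR-223-3p were to be given in each genotype comparison. No probe was named miR-486-5p. MiR-3107-5p, an earlier name of miR-486b-5p, is given in its place and is not counted in the list. No genome was needed. The reference given was used for no coordinates.

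After the few detected miRNAs of batch 2 had been seen, the 23 batch 1 arrays were also fitted alone, scaled on the 85 miRNAs detected on each of them, with 16 residual degrees of freedom. On that scale 22.4% of values lay at the floor and the array factors spanned 13.2 times. A permutation test of each mouse's mean over a list shuffled genotype within age and batch 100000 times, with log2 absorbance as a covariate. It was added after camera's calls had been seen, and so was the removal of each array's linear trend with GC content of the probe sequence. The alternatives fixed in advance changed the absorbance term, batch term, slide block, background, scaling, signal summary, filter, array weights and arrays used, and replaced the scanner values by the deposited table. Slide was entered as a random block beside batch and as a fixed block in place of batch. The fit with the fixed block has no batch term.

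Values in the deposited table were set against each array's scanner values in 12 ways. No single way tied the table to the arrays. Before centring each miRNA, own arrays ranked first in at most 19 of 23 batch 1 columns and in 0 of 13 batch 2 columns, and after it in at most 13 of 23 and 11 of 13. The scale and any centring between its arrays stay unknown. In simulated data with the real group sizes and spread and 223 miRNAs, a log2 change of 1 was found in 86.8% of changed miRNAs for the average genotype effect, 61.3% at 6 weeks, 58.8% at 12 weeks and 48.0% at 24 weeks. For a log2 change of 2 the figures were 100%, 96.3%, 94.3% and 90.8%. Each run changed 40 of the 223 miRNAs by a log2 of 1 and another 40 by a log2 of 2. With so many changed the adjusted threshold is easier to pass, so these shares overstate what is found when few miRNAs change. The simulation held neither floors nor the extra noise of batch 2. Other tests used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. For arrays, precision is limited by their number.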

Results

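Circulating miRNA was profiled in plasma of female BALB/c mice that carried the MMTV-NeuT transgene (NeuT+), an activated rat Erbb2 oncogene under a mammary tumour virus promoter that causes spontaneous mammary carcinoma, and of non-transgenic siblings (NeuT-). At 6 weeks of age there were 9 NeuT- and 6 NeuT+ mice, at 12 weeks 6 and 6, and at 24 weeks 5 and 4. The labels divide the 36 arrays into batch 1, with 23 arrays, and batch 2, with 13. All 12 mice aged 12 weeks were in batch 1. At 24 weeks batch 1 held 1 NeuT- and 2 NeuT+ mice. Each array was a separate mouse, and the number of arrays limits the precision. The comparisons ask how the circulating miRNA profile differs with the transgene and with age.

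Batch 2 plasma gave far fewer detected miRNAs than batch 1 plasma. Of 1247 miRNAs, batch 1 arrays detected a median of 234 and up to 522, and batch 2 arrays 2 to 88, with a median of 24. Among NeuT- mice of 6 weeks, batch 2 arrays detected 37.2 ± 33.996 (SD, n = 5) and batch 1 arrays 205.75 ± 48.1 (SD, n = 4), with a two-sided exact permutation p = 0.0159 and an adjusted p = 0.167 over 21 such comparisons. Median summed signal was 2699.8 in batch 2 and 105475 in batch 1. NeuT+ and NeuT- mice of 1 batch did not differ in detected miRNAs past the threshold. At 12 weeks the means were 301 ± 113 (SD, n = 6) and 236 ± 39.0 (SD, n = 6), exact permutation p = 0.186, adjusted p = 0.554. In batch 1 at 6 weeks they were 186 ± 42.9 (SD, n = 4) and 205.75 ± 48.1 (SD, n = 4), exact permutation p = 0.571, adjusted p = 0.706. The tests in batch 2 at 6 and 24 weeks, with 21 and 15 possible splits, were too small to pass. Batch 1 at 24 weeks held 1 NeuT- mouse and was not tested. Absorbance at the haemoglobin band, the read-out of haemolysis, ranged from 0.051 to 0.837 over all mice. The mice labelled as not haemolysed were all NeuT- mice of batch 2. Mean absorbance in NeuT+ and NeuT- mice was 0.38 and 0.30 at 6 weeks, 0.45 and 0.39 at 12 weeks and 0.37 and 0.26 at 24 weeks. The largest log2 difference between genotypes within a batch was 1.90, in batch 2 at 6 weeks, exact permutation p = 0.286, adjusted p = 0.554. The genotype effects thus rely on the absorbance term to set haemolysis aside. Erythrocyte miRNAs did not follow absorbance past the threshold, as given below, so how well the term does this stays open.

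**Figure D1:**
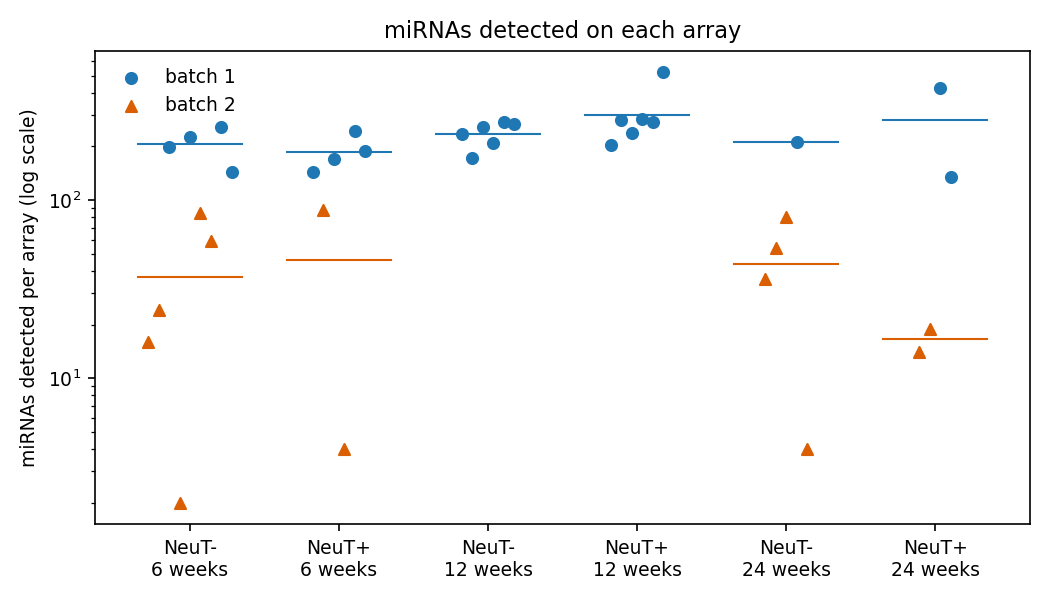
Number of miRNAs detected on each array (log scale) by genotype and age. Each point is 1 mouse, circles are batch 1 and triangles batch 2, and short lines are means of a batch within a group. Every batch 2 array, at 2 to 88, lies below every batch 1 array, of which the highest is at 522.

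Averaged over the 3 ages, miRNAs abundant in erythrocytes stood lower in NeuT+ than in NeuT- plasma, although no single miRNA passed the threshold. All 6 tested members of the erythrocyte and haemolysis list had negative differences, with a median log2 difference of -0.74, although 1 of them, miR-92a-3p, lay at the floor of the scale in every NeuT+ mouse and in every NeuT- mouse of 12 and 24 weeks. The log2 difference was -0.95 ± 0.37 (SE) for miR-451a, which matures in red cell precursors without Dicer, -0.75 ± 0.26 for miR-16-5p, -0.72 ± 0.26 for miR-15b-5p and -0.77 ± 0.30 for miR-144-3p, which shares a transcript with miR-451a. Mean miR-451a at 12 weeks was 2.07 ± 0.46 (SD, n = 6) in NeuT- and 1.43 ± 0.65 (SD, n = 6) in NeuT+ on the scaled log2 axis, and at 24 weeks 0.86 ± 1.56 (SD, n = 5) and -0.46 ± 0.93 (SD, n = 4). Camera gave the list an adjusted p = 1.32e-06, but adjusted p = 0.0674 with an estimated correlation. Adjusted over the list alone, 4 of the 6 members passed. A permutation test of each mouse's list mean, added after camera's calls had been seen, gave a log2 difference of -0.54 over 36 mice, p = 0.00196, adjusted p = 0.0235. Within batches on the same scale it gave -0.37 in batch 1, permutation p = 0.0341, adjusted p = 0.194, with -0.44, permutation p = 0.0928, adjusted p = 0.320 on the scaling of batch 1 alone, and -0.95 in batch 2, permutation p = 0.0488, adjusted p = 0.293. Of the 13 batch 2 arrays miR-451a was detected on 10, miR-144-3p on 7, miR-16-5p on 6, miR-15b-5p on 5, miR-25-3p on 3 and miR-92a-3p on 0. Much of the batch 2 difference is therefore of scaled background. With slide as a fixed block in place of batch, the list median was -0.67 and camera's adjusted p = 9.78e-05. That fit lacks the batch term. Scan day as a block gave -0.69. Batch 1 alone with its own scaling gave a median of -0.64, camera adjusted p = 0.0593, and miR-451a is 1 of the 7 miRNAs that set the common scaling. Across the tested miRNAs, which are not independent replicates, this genotype effect had a Spearman rho of 0.365 with GC content. With each array's GC trend removed the list median was -0.61, camera adjusted p = 0.000124.

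**Figure D2:**
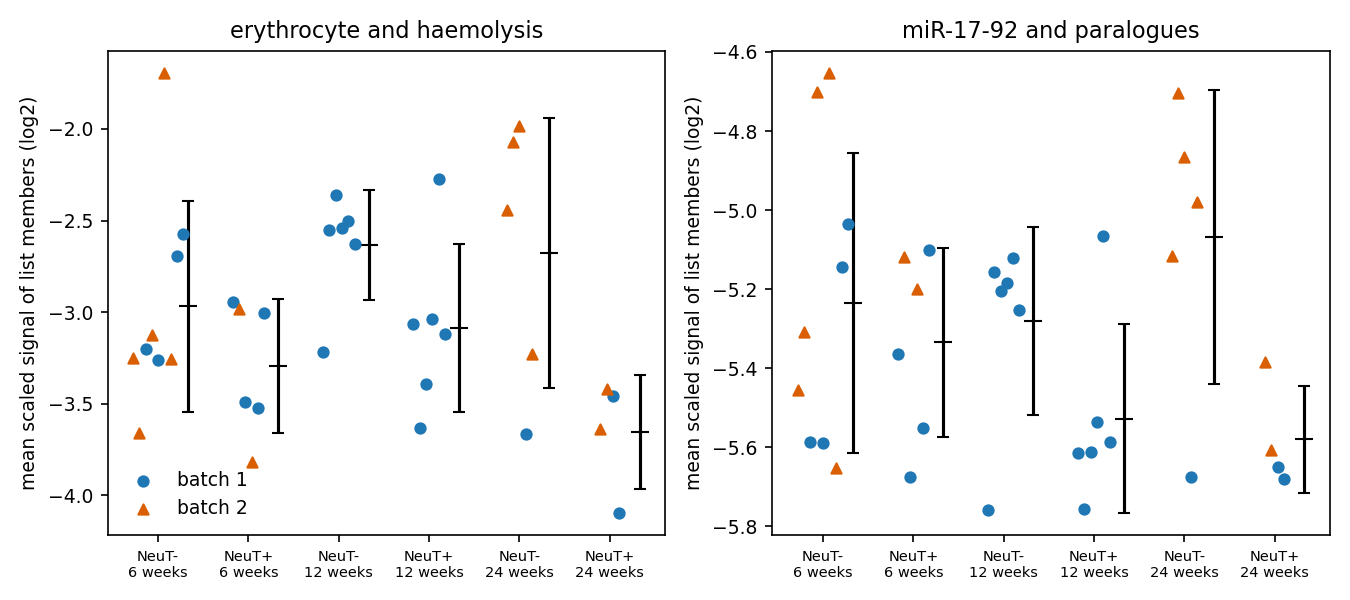
Mean scaled log2 signal over the tested members of the erythrocyte and haemolysis list (left, 6 members) and of the miR-17-92 and paralogues list (right, 9 members) in each mouse, by genotype and age. Circles are batch 1, triangles batch 2, and the black bars are group means ± SD. Batch 2 mice spread more widely than batch 1 mice.

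The miR-17-92 and paralogues list, clusters that promote proliferation of haematopoietic and tumour cells, had 8 of 9 tested members negative in the average genotype effect, and the last, miR-17-5p, lay at the floor on all 36 arrays. At 12 and at 24 weeks 3 of the 9 lay at it in every mouse, so not all of the negative averages are measured at each age. The list shares miR-92a-3p and miR-25-3p with the erythrocyte list, so the shifts of these lists are not independent. The miR-17-92 median was -0.34, with camera's adjusted p = 0.00137 and adjusted p = 0.126 with an estimated correlation. Its largest member difference was that of miR-20b-5p, -0.61 ± 0.22 (SE). The permutation test of list means gave -0.26, adjusted p = 0.0495. In batch 1 it gave -0.15, permutation p = 0.170, adjusted p = 0.503, and on the scaling of batch 1 alone -0.27, permutation p = 0.182, adjusted p = 0.415. Neither passed, though the difference on the scaling of batch 1 alone was similar in size to that over all mice. The -0.50 in batch 2, permutation p = 0.00977, adjusted p = 0.117, is mostly a difference of scaled background, as 4 of the 9 members were detected on 0 and none on more than 3 of the 13 batch 2 arrays. Slide as a block gave a median of -0.30, and the median was 0.0048 without scaling between arrays and 0.36 with the deposited values, where the median over all tested miRNAs was 0.41. Of the let-7 family, miRNAs that repress growth genes, 7 of 8 members were negative, with a median of -0.18 and camera's adjusted p = 0.0711. In batch 1 with its own scaling 8 of 8 were negative, with a median of -0.52, camera's adjusted p = 0.000992 and adjusted p = 0.645 with an estimated correlation. The permutation test of list means there gave -0.40, p = 0.0416, adjusted p = 0.250, not past the threshold.

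No other list passed in the average genotype effect, and adjusted over the list alone 0 members of any of them passed with limma. The median log2 difference was 0.045 for the 5 platelet and endothelium members, -0.18 for the 3 myeloid members, 0.0054 for the 2 lymphoid members, -0.12 for the 3 liver members and -0.20 for the 5 epithelium members. It was -0.038 for the 4 breast tumour oncomiRs, 0.0088 for the 5 breast tumour suppressor miRNAs, -0.11 for the 8 members of the miR-30 and miR-29 families and 0.033 for the 3 members of the Dlk1-Dio3 cluster. Camera's adjusted p was 0.384 for the myeloid list and 0.740 for each of the others. Among named miRNAs that did not pass, miR-21a-5p, raised in many carcinomas, was at -0.46 ± 0.29 (SE), miR-122-5p, the main hepatocyte miRNA, at -0.12 ± 0.26, miR-223-3p, a neutrophil miRNA, at -0.17 ± 0.27 and miR-3107-5p at -0.32 ± 0.23. Limma called 0 of the tested miRNAs, with 16 at an unadjusted p under 0.05 and a smallest adjusted p = 0.496. The miRNAs with the smallest p and positive differences were miR-6394 (0.51 ± 0.20), miR-760-3p (0.42 ± 0.17), miR-130a-3p (0.39 ± 0.16), miR-24-3p (0.54 ± 0.23) and miR-546 (0.18 ± 0.08), none of them past the threshold. Array weights gave 18 calls, and 17 of 100 splits of the mice gave at least as many with weights.

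At 6 weeks, before the carcinomas of this model are large, no miRNA differed between NeuT+ and NeuT- mice past the threshold. Erythrocyte and haemolysis members had a median log2 difference of -0.42 and camera's adjusted p = 0.129. MiR-451a was at -0.75 ± 0.56 (SE), miR-16-5p at -0.44 ± 0.40, miR-144-3p at -0.68 ± 0.46, miR-21a-5p at -0.89 ± 0.45, miR-122-5p at -0.63 ± 0.39, miR-223-3p at 0.13 ± 0.41 and miR-3107-5p at 0.00 ± 0.36. The smallest p among lower miRNAs were those of miR-200b-3p (-0.61 ± 0.26), miR-378a-3p (-0.64 ± 0.28), miR-101b-3p (-0.55 ± 0.24), miR-222-3p (-0.34 ± 0.15) and miR-6386 (-0.57 ± 0.26). Among higher miRNAs they were those of miR-5097 (0.54 ± 0.27), miR-134-5p (0.31 ± 0.16), miR-6239 (0.11 ± 0.07), miR-126-3p (0.60 ± 0.38) and miR-2861 (0.78 ± 0.50). The lower miRNAs named were detected on batch 1 arrays only. Of these, miR-200b-3p, miR-378a-3p, miR-101b-3p and miR-222-3p lay at the floor in all 6 NeuT+ mice. MiR-200b-3p, miR-101b-3p and miR-222-3p also lay at it on all 23 batch 1 arrays, so their differences come from scaled background in batch 2. Limma called 0 miRNAs, with 9 at an unadjusted p under 0.05 and a smallest adjusted p = 0.947. In batch 1 with its own scaling it called 0, with 1 at an unadjusted p under 0.05.

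At 12 weeks the erythrocyte, miR-17-92 and let-7 lists stood lower in NeuT+ plasma, and no single miRNA passed. The erythrocyte median was -0.62, with 6 of 6 members negative and camera's adjusted p = 2.16e-05, and adjusted p = 0.146 with an estimated correlation. The miR-17-92 median was -0.35, with 8 of 9 negative and adjusted p = 0.00283, and adjusted p = 0.168 with an estimated correlation. The let-7 median was -0.33, with 8 of 8 negative and adjusted p = 0.0345, and adjusted p = 0.868 with an estimated correlation. Of these members 1 erythrocyte, 3 miR-17-92 and 1 let-7 member lay at the floor in all 12 mice and have no measured direction, and a further 3 let-7 members lay at it in all 6 NeuT+ mice. The other 5, 6 and 7 members were negative. No member of these lists passed with limma (0 adjusted over the list alone). Without scaling the miR-17-92 and let-7 medians were 0.13 and 0.10, where the median over all tested miRNAs was 0.28, and with the deposited values all 3 list medians were positive, at 0.23, 0.57 and 0.62 against 0.67 over all. MiR-16-5p was at -0.69 ± 0.41 (SE), miR-451a at -0.61 ± 0.59, miR-144-3p at -0.62 ± 0.48, miR-3107-5p at -0.33 ± 0.37, miR-21a-5p at -0.13 ± 0.47 and miR-223-3p at -0.01 ± 0.43. MiR-122-5p lay at the floor in all 12 mice, as did 71 of the tested miRNAs at this age, and so has no measured difference. Others lower without passing were miR-5097 (-0.56 ± 0.28), miR-106b-5p (-0.44 ± 0.27), miR-15b-5p (-0.64 ± 0.41) and miR-20a-5p (-0.55 ± 0.38). Higher without passing were miR-1a-3p, a muscle miRNA (1.01 ± 0.59), miR-5128 (0.66 ± 0.54), miR-3473e (0.62 ± 0.55), miR-5105 (0.51 ± 0.58) and miR-5115 (0.06 ± 0.08). Limma called 0 miRNAs, with 0 at an unadjusted p under 0.05. In batch 1 with its own scaling, which holds all 12 of these mice, it called 0 with 21 at an unadjusted p under 0.05, and the lists had medians of -0.66, -0.49 and -0.48 with camera's adjusted p = 0.354, 0.160 and 0.0955. Array weights gave 29 calls, and 14 of 100 splits gave at least as many with weights.

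At 24 weeks, an age at which NeuT+ females of this model usually carry tumours, 3 miRNAs passed as higher in NeuT+ plasma, each with adjusted p = 0.0377 by limma. They were miR-697 (1.56 ± 0.41, SE), miR-760-3p (1.20 ± 0.32) and miR-6394 (1.39 ± 0.37). All 3 were detected on 0 of the 13 batch 2 arrays, which held 6 of the 9 mice compared. Of the 23 batch 1 arrays miR-697 lay at the floor of the common scale on 21, miR-760-3p on 20 and miR-6394 on 14. Among the 3 batch 1 mice with their own scaling the differences were -1.07 ± 0.49, -1.40 ± 0.52 and -1.31 ± 0.55, opposite in direction but set by a single NeuT- mouse. With slide or scan day as a block 0 miRNAs passed, and without NeuT+ replicate 1 also 0. Without NeuT+ replicate 3 the count was 14. MiR-24-3p (1.49 ± 0.43) and miR-150-3p (1.10 ± 0.32) came next, not past the threshold. Limma gave 32 miRNAs at an unadjusted p under 0.05.

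The erythrocyte list at 24 weeks had a median log2 difference of -1.10, with 5 of 6 members negative and 1 at the floor in all 9 mice, camera's adjusted p = 6.24e-05 and adjusted p = 0.178 with an estimated correlation. MiR-451a was at -1.50 ± 0.69 (SE), miR-16-5p at -1.13 ± 0.49, miR-15b-5p at -1.12 ± 0.48, miR-25-3p at -1.08 ± 0.46 and miR-144-3p at -1.01 ± 0.57, none of them past the threshold. Over the 13 batch 2 arrays miR-25-3p was detected on 3, miR-15b-5p on 5, miR-16-5p on 6, miR-144-3p on 7 and miR-451a on 10. Most mice compared were in batch 2, so part of these differences is of scaled background. The miR-17-92 list had a median of -0.32, with 7 of 9 negative, of which 6 were measured above the floor in at least 1 mouse, adjusted p = 0.00329 and adjusted p = 0.178 with an estimated correlation. Of either list 0 members passed adjusted over the list alone. Batch 1 arrays alone on the common scaling turned both medians, to 0.050 and 0.10, where the median over all tested miRNAs was 0.37. The miR-17-92 median was also positive with normexp (0.27), without scaling (0.20) and with the deposited values (1.36), which gave 0.39 for the erythrocyte list against 1.21 over all tested miRNAs. MiR-20b-5p was at -1.12 ± 0.41, miR-3067-3p at -1.71 ± 0.67, miR-21a-5p at -0.37 ± 0.55, miR-122-5p at 0.31 ± 0.48, miR-223-3p at -0.62 ± 0.51 and miR-3107-5p at -0.64 ± 0.44.

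The genotype effect did not differ between ages past the threshold for any miRNA. The smallest p belonged to miR-697, with a genotype effect larger by 1.81 ± 0.51 (log2, SE) at 24 than at 6 weeks, miR-27b-3p (1.35 ± 0.39), miR-150-3p (1.13 ± 0.40), miR-3099-3p (1.84 ± 0.62) and miR-760-3p (1.07 ± 0.40). With negative differences the smallest p were those of miR-5097 (-0.67 ± 0.41), miR-126-3p (-1.33 ± 0.58), miR-3067-3p (-1.53 ± 0.83), miR-25-3p (-1.10 ± 0.58) and miR-139-3p (-0.88 ± 0.62). Limma's F test called 0 miRNAs, with 14 at an unadjusted p under 0.05 and a smallest adjusted p = 0.365. The miR-697 and miR-760-3p differences were -1.57 ± 0.57 and -1.91 ± 0.60 in batch 1 with its own scaling.

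In NeuT- mice no miRNA differed between 12 and 6 weeks past the threshold, and camera called 3 lists as higher at 12 weeks, each turned in direction by at least 1 other setting. The myeloid list, miR-223 and miR-142 of neutrophils and other leukocytes, had a median of 0.56 with 3 of 3 positive, camera's adjusted p = 0.00762 and adjusted p = 0.202 with an estimated correlation. The erythrocyte list had 0.38 with 5 of 6 positive, and the miR-30 and miR-29 list 0.083 with 5 of 8 positive, each with adjusted p = 0.00916 and adjusted p = 0.308 with an estimated correlation. Of these lists 0 members passed adjusted over the list alone. MiR-29b-3p was at 0.69 ± 0.38 (SE), miR-3106-5p at 1.00 ± 0.52, miR-126-3p at 0.71 ± 0.40, miR-6537-3p at 0.65 ± 0.37 and miR-5119 at 0.96 ± 0.58, and miR-208a-5p at -1.21 ± 0.63, miR-145a-5p at -0.24 ± 0.12, miR-6238 at -0.75 ± 0.43, miR-1224-5p at -0.89 ± 0.52 and miR-328-5p at -0.68 ± 0.40, none past the threshold. Limma called 0 miRNAs, with 0 at an unadjusted p under 0.05, and in batch 1 with its own scaling 0, with 38. Without the batch term the myeloid median was -0.18 and the erythrocyte median -0.0018. With slide as a fixed block in place of batch, a fit that also lacks the batch term, the myeloid median was -0.16. With normexp the miR-30 and miR-29 median was -0.17. After each array's trend with GC content was removed, camera's adjusted p was 0.0598 for the erythrocyte and 0.129 for the miR-30 and miR-29 list.

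Between 24 and 6 weeks in NeuT- mice no miRNA and no list passed. The miRNAs with the smallest p were miR-3067-3p (1.46 ± 0.56, SE), miR-3572-5p (0.39 ± 0.16), miR-139-3p (0.98 ± 0.42), miR-3102-5p (1.30 ± 0.55) and miR-126-3p (0.90 ± 0.39) among positive differences. Among negative ones they were miR-6408 (-0.88 ± 0.30), miR-6386 (-0.69 ± 0.27), miR-378d (-0.43 ± 0.17), miR-200b-3p (-0.66 ± 0.27) and miR-27b-3p (-0.64 ± 0.27). These negative ones were detected on batch 1 arrays only. MiR-6386, miR-378d, miR-200b-3p and miR-27b-3p lay at the floor in all 5 NeuT- mice of 24 weeks. Their differences thus rest at least in part on scaled background. Limma called 0 miRNAs, with 22 at an unadjusted p under 0.05 and a smallest adjusted p = 0.423. Adjusted over the list alone, 3 of 5 platelet and endothelium members passed. Of the 5, 4 had negative differences and 2 lay at the floor in every NeuT- mouse of 24 weeks. Over the 13 batch 2 arrays miR-126-3p and miR-24-3p were each detected on 1, and miR-221-3p, miR-222-3p and miR-26a-5p on 0. Batch 2 held 4 of the 5 NeuT- mice of 24 weeks, so part of these list differences is of scaled background. With slide as a block 2 miRNAs passed.

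In NeuT+ mice no miRNA differed between 12 and 6 weeks past the threshold. MiR-3544-3p had the smallest p, at -1.49 ± 0.43 (SE) with limma's adjusted p = 0.278, followed by miR-3963 (-1.24 ± 0.46), miR-5097 (-0.71 ± 0.29), miR-5132-5p (-0.86 ± 0.35) and miR-5107-5p (-1.33 ± 0.58). Higher without passing were miR-3106-5p (1.24 ± 0.53), miR-1a-3p (1.33 ± 0.60), miR-5119 (1.03 ± 0.59), miR-29c-3p (0.65 ± 0.40) and miR-451a (0.96 ± 0.60). Limma called 0 miRNAs, with 11 at an unadjusted p under 0.05, and in batch 1 with its own scaling 0, with 47. Calls were 47.5% of the tested miRNAs without scaling and 86.1% with the deposited values.

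Between 24 and 6 weeks in NeuT+ mice the erythrocyte and miR-17-92 lists stood lower at 24 weeks, with medians of -0.48 and -0.34. With the deposited values they were 0.40 and 1.48, and the miR-17-92 median was 0.36 with normexp and 0.26 without scaling. These values are not set against the median over all tested miRNAs, so they do not show where the lists stood relative to the rest. All 6 erythrocyte members were negative, 1 of them at the floor in every mouse compared, with camera's adjusted p = 0.00451 and adjusted p = 0.434 with an estimated correlation. Of the miR-17-92 list 8 of 9 were negative and 2 of the 9 lay at the floor in every mouse compared, with adjusted p = 0.00107 and adjusted p = 0.173 with an estimated correlation. Adjusted over the list alone, 0 members of either passed. MiR-760-3p (1.09 ± 0.30, SE), miR-3106-5p (2.06 ± 0.58), miR-697 (1.30 ± 0.39), miR-150-3p (0.98 ± 0.30) and miR-666-5p (0.60 ± 0.20) were higher, and miR-5097 (-0.73 ± 0.31), miR-20b-5p (-0.68 ± 0.39), miR-6239 (-0.12 ± 0.08), miR-3963 (-0.79 ± 0.50) and miR-504-3p (-0.36 ± 0.23) lower, without passing. Limma called 0 miRNAs, with 34 at an unadjusted p under 0.05 and a smallest adjusted p = 0.105. Batch 1 arrays alone with their own scaling, with 2 mice at 24 weeks, gave 17 calls, 3 higher and 14 lower, among them miR-16-5p at -1.99 ± 0.60 and miR-3107-5p at -1.07 ± 0.31. These calls rest on NeuT+ replicate 4 of 24 weeks, as 0 passed without it, with miR-16-5p at -0.62 ± 0.62, and 66 passed without replicate 3, with miR-16-5p at -3.31 ± 0.61, where the lone mouse left is assumed to vary like the other groups.

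Within groups, erythrocyte miRNAs did not follow the absorbance past the threshold. The slope per log2 unit of absorbance was -0.14 ± 0.22 (SE) for miR-451a, 0.28 ± 0.15 for miR-16-5p, 0.24 ± 0.18 for miR-144-3p and 0.41 ± 0.15 for miR-15b-5p. Limma called 11 miRNAs, 8 with positive and 3 with negative slopes. The largest were miR-3472 at -0.72 ± 0.22, miR-6394 at -0.48 ± 0.12, miR-184-3p at 0.44 ± 0.13, miR-292-5p at 0.40 ± 0.10 and miR-200b-3p at 0.38 ± 0.10. The others were miR-101b-3p, miR-3964, miR-222-3p, miR-192-5p, miR-3470a and miR-26a-5p. Of the 11, 10 were detected on 0 batch 2 arrays. On the common scaling miR-101b-3p, miR-192-5p, miR-200b-3p, miR-222-3p, miR-26a-5p and miR-3964 lay at the floor on all 23 batch 1 arrays. MiR-184-3p, miR-292-5p and miR-3470a lay at it on 22. The slopes of these miRNAs thus come mostly from scaled background in batch 2. Adjusted over the list alone, 3 platelet and endothelium members, 2 liver, 2 epithelium, 2 oncomiR and 2 miR-17-92 members passed, and no list passed with camera. Without NeuT- replicate 4 of 6 weeks 1 miRNA passed, with slide as a block 1, and in batch 1 with its own scaling 1, miR-5097 at -0.75 ± 0.17. Another 6 relations to absorbance were examined over all mice of a batch, pooled over genotype and age, so they are not within groups. Of the 6, 1 passed, that of the array's log2 summed signal in batch 1, with a Spearman rho of 0.613 over 23 mice, permutation p = 0.00218, adjusted p = 0.0131, and a Pearson r of 0.492, permutation p = 0.0171, adjusted p = 0.0513. Without the 2 mice farthest from the median absorbance its r was 0.447, and over the 13 batch 2 mice r was -0.274 and rho -0.124, permutation p = 0.364 and 0.684. The number of detected miRNAs had r of 0.309 in batch 1 and -0.0671 in batch 2, and the erythrocyte list mean in batch 1 r of 0.121, none past the threshold. In batch 1 the log2 ratio of miR-451a to miR-23a-3p, a common haemolysis index, had a Pearson r of 0.524 with absorbance over 23 mice, permutation p = 0.0098, adjusted p = 0.0513, and a Spearman rho of 0.365, permutation p = 0.0872, adjusted p = 0.262. For this ratio r was 0.377 without the 2 farthest mice.

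Batch 2 minus batch 1, at equal group and absorbance, gave 82 calls by limma, 70 higher and 12 lower. The direction was set by the scaling, with 0 higher and 123 lower without scaling, 1 and 114 with the percentile over all miRNAs, 3 and 119 with the total gene signal and 11 and 89 with quantile normalization, while normexp gave 219 calls, 3 of them lower. On the common scaling all 8 let-7 members passed with positive values, but 4 were detected on 0 and none on more than 4 of the 13 batch 2 arrays, so these values set scaled background against signal. Their median was 1.96, camera's adjusted p = 2e-05 and adjusted p = 0.369 with an estimated correlation. The myeloid list, with members detected on 2 to 4 batch 2 arrays, had 3 of 3 past the threshold and a median of 1.71, with adjusted p = 0.0409 and adjusted p = 0.369 with an estimated correlation. Adjusted over the list alone, 8 let-7 and 3 myeloid members passed. Without scaling the let-7 and myeloid medians were -0.80 and -1.36. The largest scaled difference was that of miR-671-3p (3.31 ± 0.43, SE), and the smallest p among lower miRNAs belonged to miR-5109 (-1.92 ± 0.45) and miR-762 (-1.18 ± 0.28).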

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

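The tests of why batch 2 arrays detected few miRNAs and of the 24-week calls were chosen after these results were seen, while the counts over other splits of the mice were planned.

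Of 42 groups of values examined, 10 held a mouse that stood apart from its group by the Dixon gap, where chance gives about 1 in 20. NeuTpos_12w replicate 6 detected 522 miRNAs, the highest of its group, with the next at 287. NeuTpos_6w replicate 4, of batch 2, had a log2 summed signal of 6.97, with the next at 14.33. This mouse also had the highest let-7 mean of its group, -3.11, and the highest mean of the miR-30 and miR-29 families, -4.09, with 4 miRNAs detected, so these too are scaled background. NeuTneg_6w replicate 4 had an absorbance of 0.837, with the next at 0.44, and a miR-30 and miR-29 mean of -3.92. It is a batch 2 array on which 2 miRNAs were detected, so its list mean is scaled background. NeuTneg_12w replicate 1 had an absorbance of 0.815, with the next at 0.386, the lowest erythrocyte list mean of its group, -3.22, and the lowest miR-17-92 mean, -5.76. NeuTpos_12w replicate 5 had the highest miR-17-92 mean of its group, -5.06.

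Few miRNAs were detected on batch 2 arrays. Failed hybridisation or scanning is argued against, since the 2 hybridisation spike-in controls compared were brighter in batch 2, with the lower of the 2 ratios at 1.34. The labelling step was not tested. On slides shared with batch 1, 12 of 12 batch 2 arrays detected fewer miRNAs than every batch 1 array of their slide. This argues against slide or scan day alone. Within the shared absorbance range 7 of 7 batch 2 arrays fell below every batch 1 array, which argues against degree of haemolysis alone in that range. Both counts had to come out so once every batch 2 array was seen to lie below every batch 1 array. They are 1 observation and not separate tests. Less miRNA on the array stays open, since the 100% of 85 miRNAs with a lower unscaled median in batch 2 had been chosen for detection on every batch 1 array, so that this share decides nothing.

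The 3 miRNAs higher in NeuT+ at 24 weeks may come from scaling arrays with little signal. None was detected in batch 2, and on the common scaling they lay at the floor on 14 to 21 of the 23 batch 1 arrays. In batch 1 with its own scaling 0 of the 3 had a positive difference, which cannot decide it, as that comparison has 1 NeuT- mouse. Of 100 splits of the 24-week mice, 29 gave at least 3 calls and the highest other gave 48, so chance could not be excluded. A biological change with the transgene at this age also stays open and untested.

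Where the real count was 0, every split gives as many, 100 of 100, and the splits say nothing on chance. This holds for the average genotype effect (highest other 8), the interaction (26), 6 weeks (7), 12 weeks (0), 12 against 6 weeks in NeuT- (6) and NeuT+ (0), and 24 against 6 weeks in NeuT- (56) and NeuT+ (44). For the 11 absorbance calls chance could not be excluded, as 16 of 100 shuffles gave as many, with 92 as the highest other, and counts several times the real one point to a structure of the samples that was not tested. For the 2 lists called in the average genotype effect it could not be excluded either, as 32 of 100 splits gave as many, with 4 as the highest other. For the 82 batch calls 2 of 100 shuffles of batch within groups gave as many, the real one included, and the other gave 85, so chance is excluded only at a share under 0.05 and not by the size of the count.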

How the results depend on the processing

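Alternatives restricted to batch 1 with its own scaling or quantile normalization, those with scan day as a block, the GC trend removed or a mouse left out in batch 1 alone, the permutation test of lists and everything on 12 against 6 weeks over both genotypes in batch 1 were chosen after seeing the data; the rest were planned. No paired analysis was possible because replicate numbers follow no label. Low signal over background in batch 2 limits every comparison that draws on it. Batch 2 held 4 of the 5 NeuT- and 2 of the 4 NeuT+ mice of 24 weeks. The 6-week genotype count of 0 held under each of its alternatives, and the average genotype, interaction and 12-week counts of 0 changed only as given here. Detection on all 36 arrays left 1 miRNA and was not fitted. Batch 2 alone has no 12-week mice and could not give the average, 12-week or interaction results. The count over both genotypes in batch 1 could not be fitted without a filter. Leaving out arrays of few detected miRNAs left the batch 1 arrays. With array weights, 17 of 100 splits gave at least as many calls for the average genotype effect, 14 at 12 weeks and 12 at 24 weeks. The median log2 genotype difference over all tested miRNAs, 0.00 on average and 0.099 at 24 weeks as reported, was 0.41 and 1.21 with the deposited values, and at 24 weeks 0.44 with normexp, 0.24 without scaling and 0.37 in batch 1 alone on the common scaling, so list medians there are to be read against it. Unless the alternative itself leaves out mice, the cause was not tested.

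Leaving out each array in turn gave counts of 0 to 0 for the average genotype effect, 6 weeks, 12 weeks, the interaction and 12 against 6 weeks in NeuT-. The range was 0 to 14 at 24 weeks (lowest without NeuTpos_24w replicate 1, highest without NeuTpos_24w replicate 3), 0 to 1 for 24 against 6 weeks in NeuT- (1 without NeuTneg_6w replicate 6), 0 to 0.448% of the miRNAs tested for 12 against 6 weeks in NeuT+ (highest without NeuTpos_6w replicate 1) and 0 to 16 for 24 against 6 weeks in NeuT+ (16 without NeuTpos_24w replicate 3). In batch 1 with its own scaling the last was 66 without NeuTpos_24w replicate 3 and 0 without replicate 4. It was 1 to 34 for absorbance (1 without NeuTneg_6w replicate 4, 34 without NeuTpos_6w replicate 2), 54 to 101 for batch (54 without NeuTneg_6w replicate 4), 2 to 4 for lists (4 without NeuTpos_24w replicate 1) and 0 to 32 for 12 against 6 weeks over both genotypes in batch 1 (0 without NeuTpos_6w replicate 5). Without NeuTneg_6w replicate 4 the slopes on absorbance of miR-3470a and miR-101b-3p turned to -0.0022 and -0.020.

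The number of lists called for the average genotype effect, 2 as reported, was 0 with an estimated correlation, 1 with normexp, without scaling, with the deposited values, in batch 1 with its own scaling, in batch 1 with its own scaling and no absorbance term and in batch 1 with its own scaling after removing the GC trend and 4 in batch 1 alone on the common scaling and without arrays of few detected miRNAs. The 24-week genotype count, 3 as reported, was 0 without the absorbance term, with haemolysis as yes or no, without the batch term, in batch 1 alone on the common scaling, with slide as a block, with normexp, with the percentile over all miRNAs, without scaling, with the total gene signal, with the mean over probes, without a filter, with the deposited values, without the 2 NeuT- mice labelled with dysplasia, without arrays of few detected miRNAs, in batch 1 with its own scaling, in batch 1 with its own scaling and no absorbance term, in batch 1 after quantile normalization, with scan day as a block, in batch 1 with its own scaling after removing the GC trend and in the 2 groups alone, 6 with linear absorbance, with detection on 50% of arrays and after removing the GC trend, 8 without the 3 CI mice, 10 without the 5 mice not haemolysed and 21 with array weights. The absorbance count, 11 as reported, was 0 with haemolysis as yes or no, in batch 1 alone on the common scaling, with normexp, with the percentile over all miRNAs, without scaling, with the total gene signal, with the deposited values, without the 3 CI mice, without arrays of few detected miRNAs, in batch 1 after quantile normalization and in batch 1 with its own scaling after removing the GC trend, 1 with slide as a block, without the 5 mice not haemolysed and in batch 1 with its own scaling, 2 without the batch term and with detection on 50% of arrays, 4 in batch 2 alone, 5 with the mean over probes, 7 with array weights, 19 with scan day as a block, 32 with linear absorbance and 102 without a filter. The count for 24 against 6 weeks in NeuT+, 0 as reported, was 1 without the 3 CI mice and without the 5 mice not haemolysed, 3 with quantile normalization, 14 in batch 1 after quantile normalization, 16 with array weights, 17 in batch 1 with its own scaling, 24 in batch 1 with its own scaling after removing the GC trend, 27 in batch 1 with its own scaling and no absorbance term, 53 in batch 1 alone on the common scaling and without arrays of few detected miRNAs and 54 with the deposited values. That for 24 against 6 weeks in NeuT-, 0 as reported, was 2 with slide as a block. As a percent of the miRNAs tested, calls for 12 against 6 weeks in NeuT+, 0 as reported, were 0.448% in batch 1 after quantile normalization, 0.897% with the percentile over all miRNAs, 1.35% with normexp, 2.24% with quantile normalization, 3.59% with the total gene signal, 8.07% in batch 1 with its own scaling and no absorbance term, 9.42% with array weights, 47.5% without scaling and 86.1% with the deposited values. The batch count, 82 as reported, was 3 with the deposited values, 46 with array weights, 219 with normexp and 472 without a filter. For 12 against 6 weeks in NeuT- it, 0 as reported, was 2 with the percentile over all miRNAs, with quantile normalization and without scaling, 3 with the total gene signal and 57 with array weights. The average genotype count, 0 as reported, was 1 with quantile normalization and 18 with array weights. The interaction count, 0 as reported, was 1 with quantile normalization and 18 with array weights. The 12-week genotype count, 0 as reported, was 1 with the deposited values, 2 with the total gene signal and 29 with array weights. The batch 1 count for 12 against 6 weeks over both genotypes, 25 as reported, was 0 on the common scaling set and over all 36 arrays, 1 with the deposited values, 9 with the percentile over all miRNAs, 14 with normexp, 15 with quantile normalization and 116 with array weights.

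In the genotype difference at 24 weeks, miR-760-3p (1.20 as reported) took -0.12 in batch 1 alone on the common scaling and without arrays of few detected miRNAs, -0.27 with the percentile over all miRNAs, -0.086 with the total gene signal, -1.40 in batch 1 with its own scaling, -1.49 in batch 1 with its own scaling and no absorbance term, -1.18 in batch 1 after quantile normalization and -1.47 in batch 1 with its own scaling after removing the GC trend. MiR-6394 (1.39 as reported) took -0.12 in batch 1 alone on the common scaling and without arrays of few detected miRNAs, -0.40 with the percentile over all miRNAs, -0.052 without scaling, -0.11 with the total gene signal, -1.31 in batch 1 with its own scaling, -1.46 in batch 1 with its own scaling and no absorbance term, -0.93 in batch 1 after quantile normalization and -1.43 in batch 1 with its own scaling after removing the GC trend. MiR-697 (1.56 as reported) took -0.12 with the percentile over all miRNAs, -0.38 with the total gene signal, -1.07 in batch 1 with its own scaling, -1.08 in batch 1 with its own scaling and no absorbance term, -1.14 in batch 1 after quantile normalization and -1.06 in batch 1 with its own scaling after removing the GC trend. In the slope on absorbance, miR-292-5p (0.40 as reported) took -0.0056 in batch 1 alone on the common scaling and without arrays of few detected miRNAs. MiR-3470a (0.19 as reported) took -0.0036 in batch 1 alone on the common scaling and without arrays of few detected miRNAs, -0.00017 with quantile normalization and -0.0015 with the total gene signal. MiR-184-3p (0.44 as reported) took -0.012 in batch 1 alone on the common scaling and without arrays of few detected miRNAs, -0.049 with the total gene signal, -0.18 in batch 1 with its own scaling and in batch 1 with its own scaling after removing the GC trend and -0.17 in batch 1 after quantile normalization. MiR-26a-5p (-0.20 as reported) took 0.23 with normexp, 0.038 without scaling, 0.016 with the mean over probes, 0.045 with the deposited values and 0.0022 without the 3 CI mice. MiR-6394 (-0.48 as reported) took 0.16 with normexp, 0.072 without scaling and 0.071 with the deposited values. MiR-200b-3p (0.38 as reported) took -0.013 with the percentile over all miRNAs, -0.0088 with quantile normalization, -0.0019 with the total gene signal, -0.14 in batch 1 with its own scaling and in batch 1 with its own scaling after removing the GC trend and -0.034 in batch 1 after quantile normalization. MiR-3964 (0.30 as reported) took -0.0035 with the percentile over all miRNAs and -0.030 with the total gene signal. MiR-101b-3p (0.33 as reported) took -0.00099 with quantile normalization, -0.00059 with the total gene signal, -0.030 in batch 1 with its own scaling and -0.037 in batch 1 with its own scaling after removing the GC trend. MiR-222-3p (0.21 as reported) took -0.0018 with the total gene signal and -0.00029 in batch 1 with its own scaling after removing the GC trend. MiR-192-5p (0.20 as reported) took -0.045 with the total gene signal, -0.11 in batch 1 with its own scaling and in batch 1 with its own scaling after removing the GC trend and -0.23 in batch 1 after quantile normalization. MiR-3472 (-0.72 as reported) took 0.073 without the 5 mice not haemolysed. For 12 against 6 weeks in NeuT+, miR-3963 (-1.24 as reported) took 2.06 with the deposited values. MiR-5097 (-0.71 as reported) took 1.38 with the deposited values. For 24 against 6 weeks in NeuT+, miR-6239 (-0.12 as reported) took 1.20 with the deposited values. MiR-504-3p (-0.36 as reported) took 1.08 with the deposited values. For both age comparisons in NeuT+ the deposited values are not set against the median over all tested miRNAs. They give no direction relative to the rest. MiR-760-3p (1.09 as reported) took -1.09 in batch 1 with its own scaling and no absorbance term and -1.08 in batch 1 with its own scaling after removing the GC trend. MiR-697 (1.30 as reported) took -0.94 in batch 1 with its own scaling and no absorbance term. In the genotype difference averaged over ages, miR-148a-3p (-0.082 as reported) took 0.30 with array weights. For 12 against 6 weeks in NeuT-, the erythrocyte and haemolysis list (0.38 as reported) took -0.0018 without the batch term. The myeloid list (0.56 as reported) took -0.18 without the batch term and -0.16 with slide as a fixed block in place of batch. The miR-30 and miR-29 families list (0.083 as reported) took -0.17 with normexp. In the genotype difference at 24 weeks, the erythrocyte and haemolysis list (-1.10 as reported) took 0.050 in batch 1 alone on the common scaling and without arrays of few detected miRNAs and 0.39 with the deposited values. The miR-17-92 and paralogues list (-0.32 as reported) took 0.10 in batch 1 alone on the common scaling and without arrays of few detected miRNAs, 0.27 with normexp, 0.20 without scaling and 1.36 with the deposited values. For 24 against 6 weeks in NeuT+, the miR-17-92 and paralogues list (-0.34 as reported) took 0.36 with normexp, 0.26 without scaling and 1.48 with the deposited values. The erythrocyte and haemolysis list (-0.48 as reported) took 0.40 with the deposited values. In the batch difference, the myeloid list (1.71 as reported) took -0.71 with the percentile over all miRNAs, -1.36 without scaling and -1.38 with the total gene signal. The let-7 family list (1.96 as reported) took -0.38 with the percentile over all miRNAs, -0.80 without scaling and -0.94 with the total gene signal. In the genotype difference averaged over ages, the miR-17-92 and paralogues list (-0.34 as reported) took 0.0048 without scaling and 0.36 with the deposited values. In the genotype difference at 12 weeks, the miR-17-92 and paralogues list (-0.35 as reported) took 0.13 without scaling and 0.57 with the deposited values. The let-7 family list (-0.33 as reported) took 0.10 without scaling and 0.62 with the deposited values. The erythrocyte and haemolysis list (-0.62 as reported) took 0.23 with the deposited values.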

Other observations

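The comparison in this part was chosen after seeing the data, from among fits to batch 1 alone, and the test of GC content was chosen after its result was seen; those of total signal, scan day and other splits were written before theirs.

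Among batch 1 mice with their own scaling, 25 miRNAs differed between 12 and 6 weeks when averaged over both genotypes, 14 higher and 11 lower by limma. The higher ones included miR-29b-3p (0.96 ± 0.21, SE), miR-29c-3p (0.84 ± 0.23) and miR-29a-3p (0.78 ± 0.20), which repress collagen genes, miR-30b-5p (0.68 ± 0.19) and miR-30c-5p (0.76 ± 0.22), miR-26b-5p (0.89 ± 0.21), miR-101a-3p (0.68 ± 0.17), and the leukocyte miRNAs miR-142-3p (1.16 ± 0.32) and miR-223-3p (0.93 ± 0.29). The lower ones included miR-149-3p (-0.71 ± 0.15), miR-3544-3p (-1.99 ± 0.50), miR-5126 (-0.55 ± 0.13) and miR-3960 (-0.43 ± 0.12). Of the miR-30 and miR-29 families, 5 of 8 members passed and 6 adjusted over the list alone, with a median of 0.72, camera's adjusted p = 0.0145 and adjusted p = 0.582 with an estimated correlation. Over the whole series with its planned scaling, 0 of the tested miRNAs passed.

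An age effect on these miRNAs is a hypothesis only. Of 100 splits of the batch 1 mice 1, the real one, gave 25 calls, and the highest other gave 2. The comparison, its arrays and its scaling were picked after seeing the data, so these splits cannot exclude chance. Scan day is argued against, as 23 of the 25 stayed past the threshold with it as a block. Total miRNA signal of the array stays open, as 9 of the 25 stayed with it as a covariate, with a median size of 0.65 against 0.79 before. GC content of the miRNA stays open, as 12 stayed after its trend was removed, with a median size of 0.59 and 23 of 25 of the same sign, and a rank correlation of -0.557 between GC and change across miRNAs before. The count was 0 without NeuTpos_6w replicate 5 and 0 on the common scaling, where the 25 had a median size of 0.58 and 22 kept their sign.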
